A study of Mus musculus with 8 samples.

How the data were processed

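The samples are total RNA of mouse myotubes, and 4 RNAs were each measured on array types A and B. Groups were taken from the labels: 1 RNA is wildtype and 1 is truncated Egr3, and the other 2 (RNA275 and RNA276) were left unassigned, since the labels give RNA275 no more than an acclimatization treatment and RNA276 nothing. The arrays of types A and B of 1 RNA were taken as the same RNA measured on different probe sets, not as replicates.

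The deposited values are intensities on a linear scale, 1 per probe set, all above 0. The software, its settings and the normalization are not given in the sources used here. In the deposited intensity values, the means after trimming 2% of probe sets from each end were 150.0 on all 8 arrays, so the arrays already shared a scale when deposited. By a rule set before the data were examined, that scale was kept as the main setting. A common mean assumes that the total signal of the RNAs is alike, and a difference shared by most genes would be removed by it. The ratio of 3' to 5' control probe sets was between 1.05 and 1.19 for beta-actin and between 0.72 and 0.832 for Gapdh over the 8 arrays.

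Gene names came from the array maker's probe sets as annotated by the platform table, matched by gene number to a RefSeq gene table of the GRCm38.p6 assembly, from which no coordinates were used. On type A, 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none. On type B the numbers were 14661, 245 and 7605. Of those with 1 symbol, 20351 and 14486 matched by gene number. Probe sets with several symbols or none were not named. Each gene was represented by its brightest probe set over the 4 arrays, on type A where it was present there and otherwise on type B, which gave 18193 genes. Signals were floored at the 50th percentile of the wildtype and truncated-Egr3 arrays pooled on type A (67.6) and at the 60th on type B (112.6), then turned to log2. A gene counted as measured when at least 1 of the 2 arrays was above the floor, which left 10307 genes (7239 on type A and 3068 on type B). Where the dimmer array was at the floor, the fold is a lower bound and is given as at least that size. Small differences of dim genes are compressed by the floor, and the order among lower bounds carries no meaning. The number of arrays limits the precision.

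No test across replicates was possible, so the comparison counts genes at least 2-fold apart. The 21 gene lists were fixed before the data were examined. The median log2 difference of each list was set against 10000 random lists of the same size, drawn from measured genes in 10 bins of mean log2 signal, and a list was said to stand apart when it lay outside the central 95%. The genes named are all members of the Egr family list, the 12 largest and 12 smallest differences among genes 2-fold apart under the deposited scale, the 3 other scalings and the higher floor, and from each list up to 4 members 2-fold apart, or the 2 largest where none was. That ranking includes lower bounds. A few more members were named after their values were seen, to show the members under 2-fold or against the direction of their list: Ddx58, Ifit2, Irf1, Mmp14, Vegfa, Myog, Myod1, Cdkn1c, Id1, Msc, Id3, Id2, Mef2c, Mcm2, Dnajb9, Pdia4, Psat1 and Asns.

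The alternatives were quantile normalization, equal medians, an intensity-dependent loess (span 0.3), a lower floor (40th and 50th percentiles), a higher floor (60th and 70th), no floor (a minimum signal of 1), thresholds of 1.5-fold and 3-fold, probe sets in place of genes, and the median over the probe sets of a gene. Leaving out probe sets marked for possible cross-hybridisation, and matching random lists on array type as well as signal, were chosen after seeing the data.

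The counting and list procedure was tested on simulated data for the comparison of wildtype against truncated Egr3, with the measured technical SD of 0.174 added to 9903 genes. It called 100 of 100 genes planted at 4-fold, 1 of 100 planted at 1.5-fold and 0 of 9703 unchanged genes. The planted genes all read more than 2 times the floor in the truncated-Egr3 RNA, so recovery of dimmer genes was not tested. The added noise held no variation between cultures, so the 0 calls give no rate of false calls between 2 cultures. A list planted with a shift of 0.5 in log2 lay at percentile 100, and 2 of 40 unchanged lists lay outside the central 95%. The unchanged lists were drawn from the same genes as the random lists, so that share was expected. It says nothing of lists whose members change together. The planted shift was large against the added noise, so its recovery was expected too. That noise comes from bright probe sets, whose median signal lay at the 86.5 percentile of type A, so dim genes vary more. Across 7131 pairs of probe sets of the same gene, the SD of the difference was 0.389. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.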

Results

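Total RNA from cultured mouse myotubes, the multinucleated muscle cells that form when muscle precursors fuse, was measured on oligonucleotide expression arrays. There were 4 RNAs, and each was hybridised to 1 array of each of 2 types, called A and B here, which gave 8 samples. The labels call 1 RNA wildtype and 1 RNA truncated Egr3. Egr3 is a zinc-finger transcription factor that is induced by activity and growth signals and is required for muscle spindles to develop. The labels do not say whether wildtype refers to the Egr3 protein or to the cells, nor how the truncated Egr3 was made or introduced. The other 2 RNAs have no stated condition that places them in a group and are not part of the comparison of wildtype with truncated Egr3; their values are given among the additional observations. The series asks which genes Egr3 regulates in myotubes, and the comparison the labels allow is the wildtype RNA against the truncated-Egr3 RNA.

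Array type A held 22690 probe sets and type B 22575, of which 64 on each were controls. On type A, 50.6% of probe sets in the wildtype RNA and 49.4% in the truncated-Egr3 RNA were above the signal floor of 67.6. On type B, 41.3% and 38.7% were above the floor of 112.6. The floors are the 50th and 60th percentiles of these 2 RNAs pooled, so the level of these shares was set by the floor. They are not detection rates. Signals of the wildtype and truncated-Egr3 RNAs had a Spearman correlation across probe sets of 0.973 on type A and 0.947 on type B. With 1 RNA per label there is no replicate check, so no p-value is given and each difference describes these 2 RNAs. The only error that could be measured was technical. For 100 probe sets present on both array types, the SD between the types was 0.246 in the log2 difference of wildtype minus truncated Egr3, which gives 0.174 for a single log2 difference. The same probe sets read on average 0.14 higher in that difference on type A than on type B, which is about the size of the smaller list medians below.

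Egr3 itself was high in both RNAs. The Egr3 probe set on type A read 769 in the wildtype RNA and 830 in the truncated-Egr3 RNA, a log2 difference of -0.11. The Egr3 probe set on type B read 1420 and 1039, a log2 difference of 0.45. The signs of the 2 probe sets differed, and neither difference reached 2-fold. A probe set outside the truncated part checks nothing about the label, and where these probe sets lie on the transcript was not analysed here. Egr1 read 1082 in the wildtype RNA and 1044 in the truncated-Egr3 RNA. Egr2 read 88.4 and 62.7, close to the floor, and 85.9 and 25.5 by its other probe set, so its log2 differences of 0.39 and 0.35 are lower bounds. Egr4 was below the floor in both. Of the NAB corepressors, which bind Egr proteins and limit their activity, Nab2 had a log2 difference of 0.48 (404 against 290) and Nab1 of 0.07. The other measured Nab1 probe set had the opposite sign, at -0.36. None of the 5 measured members of the Egr family and NAB list was called at 2-fold, and the list median was 0.07, at the 69.2 percentile of 10000 random gene lists matched on signal.

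Interferon-induced genes were far higher in the wildtype RNA than in the truncated-Egr3 RNA. Rsad2, an antiviral enzyme, read 736 against 46.6, which is at least 10.9-fold; by its 2 dimmer probe sets the log2 difference was at least 1.42 and at least 1.46. Ifit3 and Ifit1, antiviral proteins of the same family, were at least 10.2-fold and at least 9.03-fold higher. Irf7, a transcription factor that amplifies interferon production, was at least 8.15-fold higher, and the chemokine Cxcl10 at least 7.14-fold. Lower in the wildtype RNA were Tgfbi, a matrix protein, and Ddit3, a transcription factor of the stress response, which were 4.35-fold and 4.24-fold higher in the truncated-Egr3 RNA. The 3 other Tgfbi probe sets gave smaller log2 differences of -1.38, -1.30 and -0.43.

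Among 10307 genes measured, 116 were at least 2-fold higher and 55 at least 2-fold lower in the wildtype RNA. The fold is a lower bound for 49 of the higher and 9 of the lower genes, because the dimmer array was at the floor. Giving the arrays equal medians in place of the deposited scale made the counts 93 higher and 87 lower, and moved the median of all measured genes on type B from -0.03 to -0.17 in log2. In the deposited scale 67.8% of these genes were higher in the wildtype RNA, and with equal medians 51.7%. The genes at least 2-fold apart under the deposited scale, each of the 3 other scalings and the higher floor numbered 65 higher and 34 lower. Of the 38 higher genes with another measured probe set, 36 differed in the same direction there, 24 of them by at least 1.5-fold and 12 by at least 2-fold. Of the 26 such lower genes, 22 differed in the same direction, 11 by at least 1.5-fold and 10 by at least 2-fold.

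**Figure D1:**
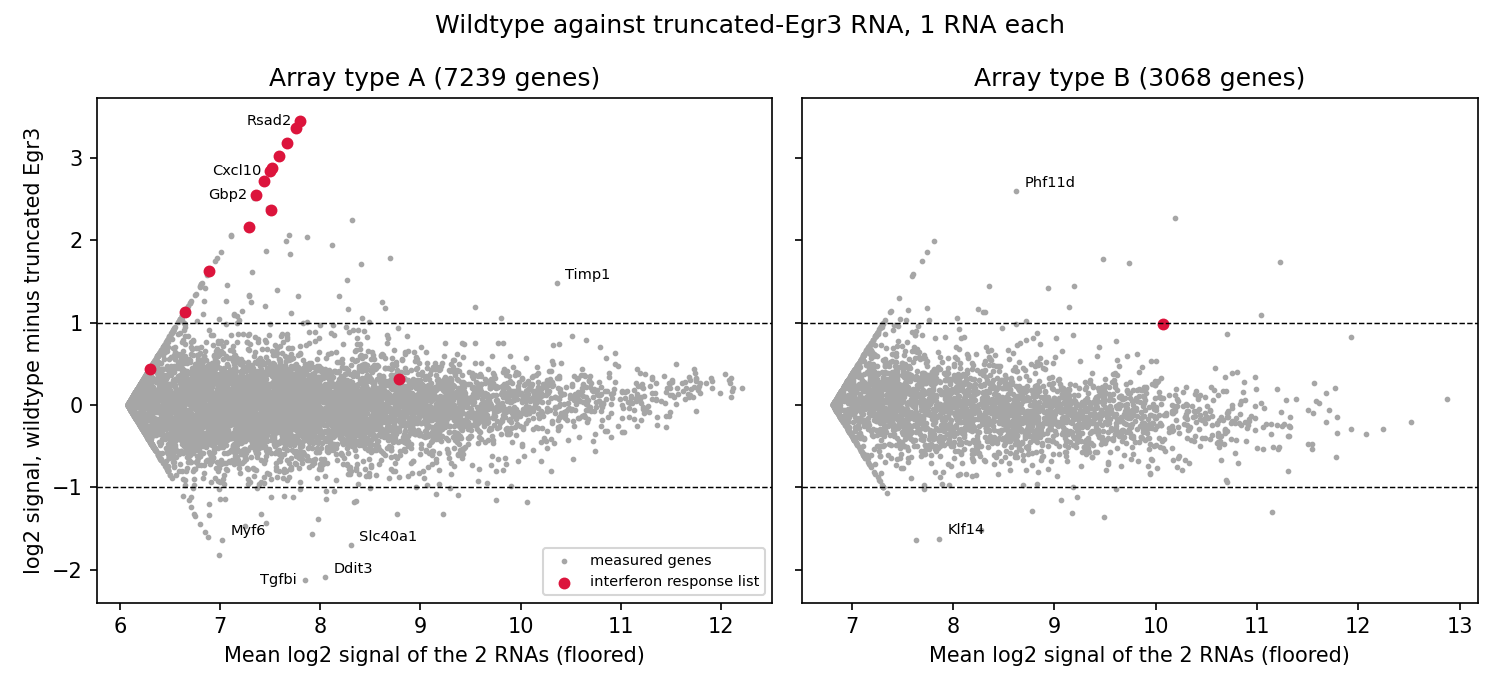
Log2 signal of the wildtype RNA minus the truncated-Egr3 RNA (vertical) against the mean log2 signal of both RNAs after the floor (horizontal), 1 point per measured gene, for array type A (7239 genes) and type B (3068 genes). Dashed lines mark 2-fold, red points are the interferon response list, and the straight edge on the left holds genes with 1 array at the floor; Rsad2 stands highest at 3.45 and Tgfbi lowest at -2.12.

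Of the 15 measured members of the interferon response list, 12 were at least 2-fold higher in the wildtype RNA and none was lower. The list median was 2.55 in log2, above all 10000 matched random lists. For 11 of the 15 members the difference is a lower bound, so the median is one too. Usp18, which restrains interferon receptor signalling, was at least 7.33-fold higher and Oasl2 at least 6.56-fold. Gbp2, a guanylate-binding protein, was at least 5.87-fold higher, and Ifih1, a sensor of double-stranded RNA, was 5.14-fold higher (413 against 80.3). The members not called at 2-fold were Ddx58 and Irf1, with log2 differences of 0.99 and 0.31, and Ifit2, for which the difference is a lower bound of 0.44. The 12 largest differences named by the fixed rule also included Phf11d (6.03-fold, 967 against 160), Rtp4 (at least 5.69-fold) and Mndal (5.22-fold, with the other probe set at 1.39 or more in log2), which are not in the list. The macrophage marker list did not stand apart: 11 of its 13 members were below the floor in both RNAs, and the other 2, Csf1r and Laptm5, had log2 differences of 0.08 and -0.16. Its median was -0.04 (percentile 42.0).

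**Figure D2:**
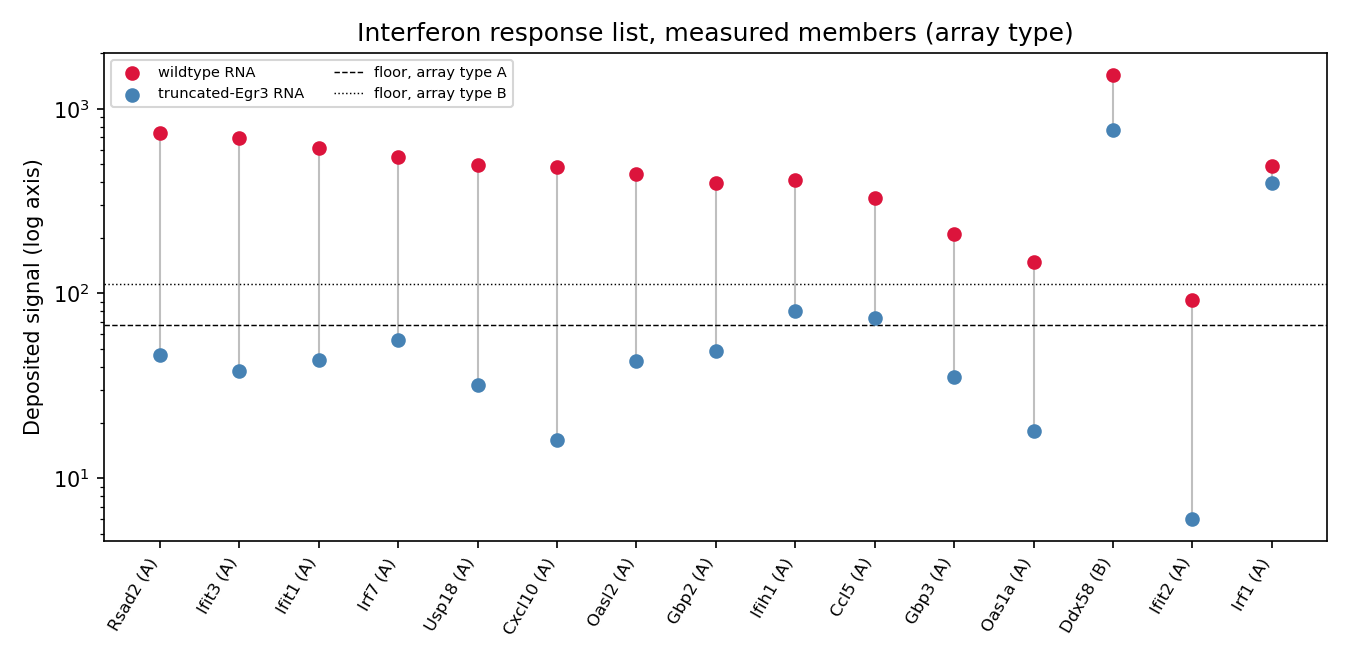
Deposited signal (log axis) of the 15 measured interferon response genes in the wildtype RNA (red) and the truncated-Egr3 RNA (blue), 1 array each, with the floors of array types A (67.6) and B (112.6) as lines. Every red point lies above its blue point, from Rsad2 at 736 against 46.6 to Irf1, whose log2 difference was 0.31.

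Genes reported as Egr targets were shifted towards higher signal in the wildtype RNA by less than the interferon genes. Of 18 measured members, 2 were at least 2-fold higher, none was 2-fold lower, and 13 had a log2 difference above 0. The median was 0.36 (percentile 99.99, with 1 of 10000 random lists as high). Smooth muscle and pericyte markers (0.46), myogenic regulators (0.35) and cell cycle genes (0.30) had medians of like size. The upward shift was therefore not particular to Egr targets, though the unfolded protein and amino acid stress list went the other way (-0.50). Tgfb1, a secreted growth factor, was 2.27-fold higher (603 against 266), but its other probe set, on type B, gave a log2 difference of 0.12. Arc, an activity-induced gene of neurons and muscle, was at least 2.06-fold higher; with the higher floor its log2 difference was 0.45, under 2-fold. The neurotrophin receptor gene Ngfr read 128 in the wildtype RNA and 15.5 in the truncated-Egr3 RNA, a log2 difference of at least 0.92. Its 2 other probe sets were below the floor in both RNAs, at 9.15 and 14.4 in the wildtype RNA. Mmp14, a membrane metalloproteinase, and Vegfa, a growth factor of blood vessels, went the other way, at -0.96 and -0.79. In the muscle spindle and neurotrophic list none of 13 measured members was called at 2-fold, but 5 of the differences are bounds; its median was 0.20 (percentile 97.6), and Etv4, a transcription factor of the Ets family, had a log2 difference of at least 0.71, with the other probe set at 0.16 or more. With the lower floor Ngfr and Etv4 passed 2-fold, at 1.54 and 1.33. That list lay within the central 95% of random lists with quantile normalization (percentile 97.2).

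Myogenic regulators were shifted towards higher signal in the wildtype RNA, with a median of 0.35 in log2, above all 10000 random lists, and 12 of 15 measured members above 0. Smooth muscle and pericyte markers (median 0.46) and housekeeping genes (median 0.20) also had higher signal in that RNA. Myog and Myod1, transcription factors of muscle differentiation, had log2 differences of 0.35 and 0.39. The largest positive differences in the list were those of Cdkn1c, Id1, Msc and Id3, at 0.74, 0.69, 0.54 and 0.50. Myog and Myod1 thus did not lead the shift, and 2 of the 15 differences are bounds. Myf6, also a myogenic transcription factor, was the 1 member that was 2-fold apart, and in the other direction, at 73.7 in the wildtype RNA against 229, or 3.10-fold higher in the truncated-Egr3 RNA. Id2 and Mef2c were also below 0, at -0.46 and -0.02. None of 45 measured sarcomere and excitation-contraction genes reached 2-fold. Trdn and Myom1, proteins of the calcium release complex and of the M band, had the largest differences at -0.67 and -0.63. The other measured Trdn probe set gave a smaller log2 difference of -0.22. The sarcomere median of 0.15 was at the 99.96 percentile in the deposited scale, but at 86.3 with quantile normalization and 92.4 with intensity-dependent loess. None of 11 postsynaptic genes was called at 2-fold, and their median was 0.15 (percentile 92.8). Agrn, which clusters acetylcholine receptors, had a log2 difference of 0.98, and Ache one of -0.47 that is a bound, with the wildtype array at the floor, and was -1.08 with the lower floor.

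Cell cycle genes had a median of 0.30, above all 10000 random lists, though none of the 24 measured members reached 2-fold and 21 were above 0. Mcm6, part of the replicative helicase, had a log2 difference of 0.97 and Pcna, the sliding clamp of DNA polymerase, of 0.75. Mcm2 went the other way, at -0.75. The 5 measured smooth muscle and pericyte markers had a median of 0.46 (percentile 99.8), with Tagln at 0.83 and Smtn at 0.59 and none at 2-fold. Among the 17 measured extracellular matrix and fibroblast genes, Timp1, an inhibitor of matrix metalloproteinases, was 2.79-fold higher in the wildtype RNA (2196 against 787), and the proteoglycan gene Dcn was 2.02-fold higher in the truncated-Egr3 RNA, though at -0.99 in log2, just under 2-fold, with quantile normalization and with loess. The median of that list was -0.09 (percentile 16.3); with quantile normalization and with loess it lay below the central 95% of random lists, at percentiles 0.77 and 0.845.

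Genes of the unfolded protein and amino acid stress responses had lower signal in the wildtype RNA. Their median was -0.50, below all 10000 random lists, and 12 of 14 measured members were below 0. Ddit3, which is induced when protein folding fails, was the member at 2-fold, 129 in the wildtype RNA against 546. Its other probe set gave a log2 difference of -1.21, a bound with the wildtype array at the floor. Dnajb9 and Pdia4, a chaperone and a disulfide isomerase of the endoplasmic reticulum, had log2 differences of -0.99 and -0.85, the latter a bound with the wildtype array at the floor, while Psat1 and Asns, enzymes of amino acid synthesis, were at 0.14 and 0.17. Other genes with large differences in this direction were Slc40a1, the iron exporter (3.26-fold higher in the truncated-Egr3 RNA, with the other probe set at -1.70), Klf14 (3.08-fold), Ppp1r3b (2.85-fold), Zfp46 (2.76-fold) and Edil3 (2.70-fold). Aspn, Ampd1 and Tcim were at least 3.53-fold, at least 3.11-fold and at least 3.03-fold higher in the truncated-Egr3 RNA. Fndc1 was 2.95-fold higher there by its type A probe set, but its type B probe set had the opposite sign, at 0.63.

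**Figure D3:**
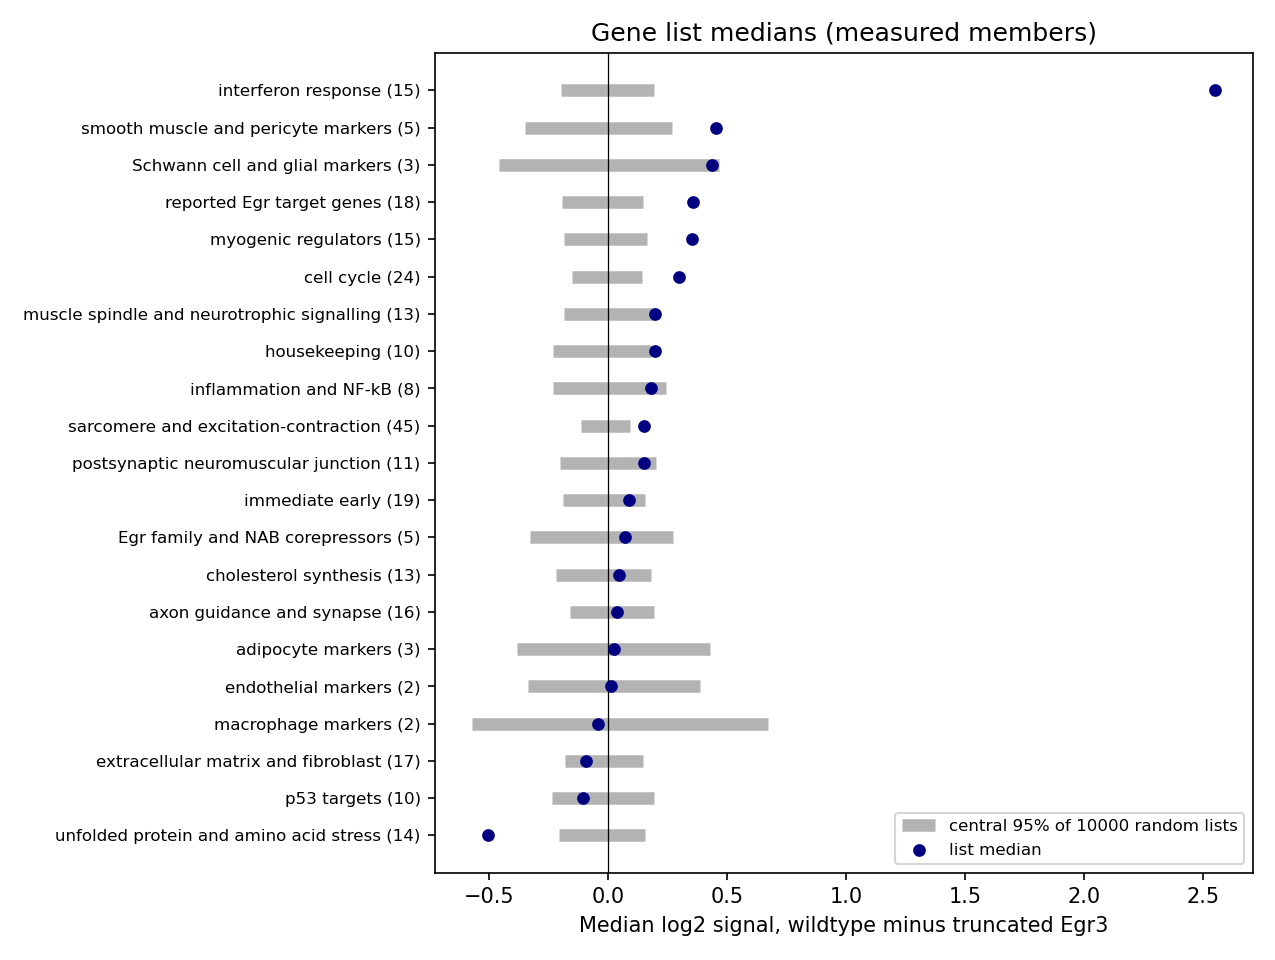
Median log2 difference, wildtype minus truncated Egr3, of each of 21 gene lists (points, with the number of measured members in brackets), set against the central 95% of medians of 10000 random lists of the same size matched on signal (bars). The interferon response list lies at 2.55 and the unfolded protein and amino acid stress list at -0.50, both outside their bars.

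The remaining lists held single genes at 2-fold or none. Ccl2, a chemokine, was at least 4.17-fold higher in the wildtype RNA, the 1 of 8 measured inflammation and NF-kB genes to reach 2-fold (median 0.18, percentile 91.9). Ccn2, a growth factor-induced matrix protein, was 2.37-fold higher and the 1 of 19 immediate early genes to do so (median 0.09, percentile 88.8). Trp53inp1 was 2.21-fold higher in the truncated-Egr3 RNA (log2 -0.91 with the higher floor) and was the 1 of 10 p53 targets at 2-fold (median -0.10, percentile 19.8). No member reached 2-fold among 13 cholesterol synthesis genes (median 0.05, percentile 71.8), 16 axon guidance and synapse genes (median 0.04, percentile 57.1), 3 Schwann cell and glial markers (median 0.44, percentile 96.7), 3 adipocyte markers (median 0.03, percentile 47.6) or 2 endothelial markers (median 0.01, percentile 44.6). Among the genes of these lists, Lpl had a log2 difference of 0.51. Robo1 and Kdr had differences of -0.61 and 0.07 that are bounds, with 1 array at the floor. Hmgcs1 had a difference of 0.57 by its brightest probe set and of -0.20, 0.11 and 0.14 by 3 others. Cnp had one of 0.87 by its brightest probe set and of 0.17 and 0.19 by 2 others. The 10 measured housekeeping genes had a median of 0.20 (percentile 98.3), with none at 2-fold and B2m, a subunit of class I histocompatibility molecules, at 0.70; with quantile normalization the percentile was 92.3. In all, 9 of the 21 lists lay outside the central 95% of random lists. For lists of independently drawn genes 1.05 would, and the lists share some genes. Members of 1 list can also change together between any 2 cultures, so more than 1.05 lists can stand apart without an effect of Egr3.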

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

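The tests on the interferon genes, and the test of the Egr3 probe sets against probe sets on both array types, were chosen after the values had been seen, as was the threshold of 2-fold above both assigned RNAs that picked out the values of RNA276; the test of Egr3 against pairs of probe sets of other genes was set before its result was seen.

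RNA276, which has no stated condition and belongs to no group, had interferon response signals above both assigned RNAs. Its list median was 2.01 in log2 above the higher of the wildtype and truncated-Egr3 RNAs, and each of the 15 measured members was above both. Rsad2 read 3413 in RNA276, 571 in RNA275, 736 in the wildtype RNA and 46.6 in the truncated-Egr3 RNA. The list medians of the 4 RNAs were 10.92 in RNA276, 8.91 in wildtype, 8.70 in RNA275 and 6.08 in truncated Egr3, where 6.08 is the floor. Scaling is argued against as the source of the difference between wildtype and truncated Egr3, since the lowest list median over the 3 other scalings was 2.52. RNA from macrophages in the wildtype culture stays open: 11 of 13 macrophage markers were below the floor in both RNAs, and the largest log2 difference of any marker, 0.079 (Csf1r), rests on too few readable markers to decide. Variation between cultures unrelated to Egr3 and an effect of the truncated Egr3 cannot be told apart, because there is 1 RNA per label while the list median ranged over 4.84 in log2 across the 4 RNAs.

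The Egr3 probe set on type A read 2627 in RNA276, 1.66 in log2 above the higher assigned RNA. The same probe set read 1454 in RNA275, 830 in truncated Egr3 and 769 in wildtype. The Egr3 probe set on type B ordered the RNAs differently, with 771 in RNA276, 1203 in RNA275, 1039 in truncated Egr3 and 1420 in wildtype. The log2 ratio of the 2 probe sets ranged over 2.65 across the 4 RNAs, while the highest such range among the 100 probe sets present on both array types was 1.19, which argues against measurement error between the array types. Of 1804 other pairs of probe sets of the same gene across the array types, all above the floor, 0.0554% (1 pair) ranged as far. Ordinary disagreement between probe sets is thus argued against as well, for the 4 RNAs together. Between wildtype and truncated Egr3 alone, the log2 differences of the 2 probe sets (type A minus type B) stood -0.56 apart. Across 7131 pairs of probe sets of the same gene, the SD of that quantity was 0.389. The opposite signs in that comparison are therefore not covered by this argument. Whether the probe sets read different parts of the transcript, or RNA from an introduced Egr3, was not tested, since probe sequences were not used here.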

How the results depend on the processing

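Leaving out probe sets marked for cross-hybridisation and matching random lists on array type were chosen after seeing the data; the other alternatives were planned. Under these alternatives no list median outside the random lists changed sign, and neither did any gene at 2-fold named by the fixed rule. The sign of the other genes at 2-fold was not followed. By its single other probe set Fndc1 had the opposite sign, at 0.63. Genes higher in the wildtype RNA numbered 116, and 185, 76 and 263 with the lower, higher and no floor, 473 and 38 at 1.5-fold and 3-fold, and 205 as probe sets; the floor changes how many dim genes can reach 2-fold. Genes lower numbered 55, and 84 and 102 with the lower and no floor, 484 and 8 at 1.5-fold and 3-fold, 151 as probe sets, and 87 with equal medians. Equal medians multiplies each array by a constant and so lowers the differences of an array type together. The median of measured genes moved from -0.03 to -0.17 on type B and from 0.01 to -0.05 on type A, which carried more genes past 2-fold lower. Without cross-hybridising probe sets 112 were higher and 47 lower. The interferon median was 2.08 with the higher floor, 3.30 with no floor and 2.17 as the median over probe sets, and the Schwann cell median 0.19 by the last. The other 142 list medians moved by less than 0.246, the SD between array types used as the tolerance. That tolerance is the spread of single probe sets, so it is wide for a list median. Several main medians, such as 0.20 for housekeeping genes, are smaller than it. The unfolded protein and amino acid stress median was -0.31 with the higher floor, against -0.50 in the main setting. Endothelial markers gave none with the higher floor. List percentiles moved to inside the central 95% for muscle spindle genes (97.2 quantile, 97.3 matched on array type), sarcomere genes (86.3 quantile, 92.4 loess) and housekeeping genes (92.3 quantile, 95.8 loess, 95.4 matched on array type), and to outside it for extracellular matrix genes (0.77 quantile, 0.845 loess) and Schwann cell markers (98.6 quantile, 98.3 equal medians, 98.5 loess); the cause was not tested. Egr3 ranged from -0.17 to -0.08 on type A and from 0.30 to 0.60 on type B. Of the values of single named genes, 66 moved by more than that tolerance and 347 did not. No paired analysis was possible because each label has 1 RNA. Genes with an array at the floor have only bounds.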

Other observations

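The split of genes by the unassigned RNAs, the hypoxia list and the tests on both were chosen after the data had been examined; the values of the unassigned RNAs for the gene lists and the correlation across genes were planned.

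Of the 116 genes at least 2-fold higher in the wildtype RNA than in the truncated-Egr3 RNA, 44 were at least 2-fold higher in RNA276 than in RNA275 and 41 at least 2-fold higher in RNA275 than in RNA276. Over all 10307 measured genes these numbers were 230 and 506. All 12 interferon list members at 2-fold were among the 44. The 41 included Vgf, a secreted neuropeptide precursor (446 in wildtype, 15.8 in truncated Egr3, 1047 in RNA275, 29.6 in RNA276), and Lingo1, a neuronal membrane protein (420, 101, 473 and 56.0 in the same order). They also included Inha, an inhibin subunit (770, 224, 1513 and 226), and the reported Egr targets Arc and Tgfb1, though the other Tgfb1 probe set went the opposite way, at 193 in RNA275 and 320 in RNA276. RNA275 was above the wildtype RNA for 38 of the 41 genes, and RNA276 for none of them. RNA276 was above the wildtype RNA for 44 of the 44 and RNA275 for 20 of them. The 41 and 44 genes were chosen for being high in 1 of these RNAs, which favours such counts. The genes higher in the wildtype RNA thus did not all move together between RNA275 and RNA276. The interferon members at 2-fold had a median of 1.67 in log2 of RNA276 minus RNA275, while 41 other genes went the other way by 2-fold. Those 41 were picked for that direction, and the conditions of these 2 RNAs are not known. The split therefore cannot decide whether a single program raised all these genes in the wildtype RNA. The labels give RNA275 no more than an acclimatization treatment and RNA276 nothing, so neither set is tied to a condition here. Across the 10307 genes, which are not independent replicates, RNA276 minus RNA275 and wildtype minus truncated Egr3 had a Pearson r of -0.12 and a Spearman rho of -0.12; over the 116 genes higher in the wildtype RNA, which were chosen on one of these differences, r was 0.39.

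Several list medians of the unassigned RNAs lay outside the range of the assigned ones. The cell cycle list median was 8.20 in RNA276, 7.66 in RNA275, 7.63 in wildtype and 7.25 in truncated Egr3. For adipocyte markers, with 3 measured, the median was 7.97 in RNA275, 6.43 in RNA276, 6.96 in wildtype and 6.93 in truncated Egr3.

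A hypothesis is that genes induced by low oxygen were lower together in the wildtype RNA than in the truncated-Egr3 RNA. The list of 33 genes came from general knowledge, after 7 of its members had been seen in these data (Ndrg1, Ankrd37, Ero1a, Slc2a3, Vegfa, Pgf and Pgk1) and before the values of the others were. Without those 7, the 23 measured members had a median log2 difference of -0.53, below all 10000 matched random lists, and 18 of them were below 0, although none was 2-fold lower. The truncated-Egr3 RNA had the highest signal of the 4 RNAs for 17 of the 23, and the wildtype RNA was above both unassigned RNAs for 14, so the wildtype RNA was not the low one among the 4. Higd1a, Egln1 and Pdk1 had log2 differences of -0.99, -0.96 and -0.75, while the glycolytic genes Ldha and Aldoa were at 0.12 and 0.14. Scaling is argued against, since the highest median over the 3 other scalings was -0.52. The shift is consistent with a shared hypoxia response, but with 1 RNA per label an effect of Egr3 and a difference between the cultures in oxygen, density or medium stay open, and neither was tested.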
